A study of Mus musculus with 5 samples.

How the data were processed

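Estrogen receptor alpha (ERα), the ligand-activated transcription factor encoded by Esr1, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the uterus of KIKO mice. As general background from outside the labels, KIKO mice carry 1 ERα allele with a mutated DNA-binding domain opposite a null allele, so that the mutant receptor is the form present. Per the labels' protocols, mice were ovariectomized, which removes the main source of endogenous estrogen, and were injected 10 to 14 days later with saline vehicle or 250 ng estradiol per mouse. Uteri were collected 1 h after injection, fixed in 1% formaldehyde for 15 minutes, and their chromatin was sheared to 300 to 500 bp on average. Each precipitation used 20 to 30 µg of chromatin. The antibodies were sc-542 for ERα and ab5095 for RNA polymerase II phosphorylated on serine-5 of its repeat domain, per the labels.

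The series lists 5 samples with 1 library in each group. Regions of the 2 ERα libraries, vehicle and estradiol, were used. The RNA polymerase II libraries and the input DNA library were not analysed here, so no background from control chromatin stands beside the values. With 1 library per group there is no replicate error. Every test below therefore compares sites in these 2 libraries, not the treatments, and sites are not independent replicates.

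Each deposited file is a list of called regions in 3 columns, chromosome, start and end, as the authors left it. It has no header, no signal height, no score and no p-value. The submitters' processing notes name build mm9, Picard 1.62, Partek 6.11.1101 and bedtools. The aligner, the rule and threshold used to call regions, any use of the input library and the number of reads are not given in the sources used here. The depth behind each region is therefore unknown, and the number and width of regions depend on depth and threshold as well as on binding. The coordinates were set against a GRCm38 gene table: 6 chromosomes in the vehicle list and 5 in the estradiol list hold a region beyond the last GRCm38 gene. GRCm38 chromosome lengths were not used, so the build rests on the submitters' notes. No region was listed more than once, and neighbouring regions of a list did not overlap.

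No mm9 sequence or annotation was used here, and coordinates were not converted between builds. The planned analyses of response elements, k-mers, promoters, exons and introns, distance to transcription start sites and gene lists were therefore not run, and regions are named by coordinate, not by gene. Coordinates are 1-based mm9 positions.

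From the regions, width and covered length were computed as end minus start of the deposited 0-based coordinates, which counts both end bases of the 1-based positions printed here. A region counted as shared when it had at least 1 bp in common with a region of the other list. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and medians carry 95% order-statistic intervals. These intervals describe sampling of sites within a library only. Chance overlap was estimated by placing every region at random 1000 times within the stretch of its own chromosome between the first and last region of either list, with its width kept. The smallest one-sided permutation p this allows is 0.001. These placements ignore unmappable sequence and the clustering of open chromatin, so a nearer reference, in which each region was shifted by 10 to 100 kb, was added after the data were seen. Median widths were compared with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05. Widths of sites called once in each list were compared by random sign flips of the paired differences. Chromosome shares were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 20 chromosomes. That test takes the lists as separate samples, although many sites are in both, so its p-values are descriptive. A region had a neighbour when another region of the same list lay within 10 kb, and clusters joined regions at most 12.5 kb apart. The neighbour and cluster measures themselves were chosen after the region lists were seen.

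The overlap procedure was tested on simulated data for the comparison of 2908 vehicle regions with the estradiol list. Of those regions 50.5% were planted in estradiol regions, and 50.9% were recovered as shared. Among 500 randomly placed lists, 27 reached p under 0.05. Those lists followed the same placement rule as the chance values, with fewer placements than in the results. This rate therefore checks the calculation only, not how well random placement stands for real regions. Distances of 200 regions were checked against a direct search and all 200 were equal.

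The rule for named sites was set before the data were examined: without an mm9 annotation, the 5 widest regions of each library, since no score was given. Alternatives set at the same time were other overlap criteria, a fixed width of 200 bp, merging of regions within 500 bp, and restriction to regions at least as wide as the median of their list. For shared against estradiol-only regions they were counting regions within 500 bp as shared and matching on width, and both were later applied to the neighbour measure. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.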

Results

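The data comprised 2 genome-wide lists of ERα-bound regions from the KIKO mouse uterus, 1 from vehicle-treated animals and 1 collected 1 h after 250 ng estradiol. ERα is the nuclear receptor through which estradiol acts on the uterus, and the receptor of this line is known for its mutated DNA-binding domain. The comparison asks where this receptor sits on chromatin without added hormone and where it sits after hormone. No replicates were available, and sequencing depth was unknown.

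Many more ERα regions were listed after estradiol than after vehicle. The vehicle list held 2908 regions and the estradiol list 18990, which is 6.53 times as many. The estradiol regions covered 7.54 Mb in total and the vehicle regions 0.780 Mb, a 9.66-fold difference in covered length. Regions were found on chromosomes 1 to 19 and X in both lists. No test of the treatment can be made from 1 library each.

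Most vehicle regions recurred after estradiol, whereas most estradiol regions had no vehicle counterpart. Of the 2908 vehicle regions, 2037 (70.0%, 95% interval 68.3 to 71.7%) shared at least 1 bp with an estradiol region. Of the 18990 estradiol regions, 2025 (10.7%, 95% interval 10.2 to 11.1%) shared sequence with a vehicle region, and 16965 did not. Nearly all shared sites had 1 region in each list, so 2908 vehicle regions could match only a minority of the 18990. The low estradiol share therefore follows largely from the difference in list length. Random placement of the vehicle regions on their chromosomes gave 15.7 overlapping regions on average and at most 29 in 1000 placements (one-sided permutation p = 0.001, the smallest possible). The observed overlap was 129 times the placed mean. When regions were instead shifted by 10 to 100 kb, which keeps them in the same neighbourhoods, 51.6 overlapped on average and the observed number was 39.5 times higher (one-sided permutation p = 0.001, again the smallest possible). Sites found in both lists lay at nearly the same position. Among 2013 sites with exactly 1 region in each list, the midpoints were a median of 22.5 bp apart, and in 1542 of them (76.6%) the vehicle region lay wholly inside the estradiol region.

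Shared sites were the wider ones in both libraries. Vehicle regions with an estradiol counterpart had a median width of 280 bp, and the 871 without one had a median of 191 bp, a difference of 89 bp (two-sided permutation p = 1e-05, the smallest possible). In the quintile of narrowest vehicle regions, 120 to 177 bp, 37.6% (33.7 to 41.7%) were shared. The share was 93.8% (91.5 to 95.6%) in the quintile of widest vehicle regions, 343 to 1712 bp. Estradiol regions behaved alike at a lower level, with 5.27% (4.58 to 6.02%) shared in the narrowest quintile and 18.6% (17.4 to 19.9%) in the widest. Of the 100 widest vehicle regions 93 were shared, and of the 100 widest estradiol regions 27 were shared.

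**Figure D1:**
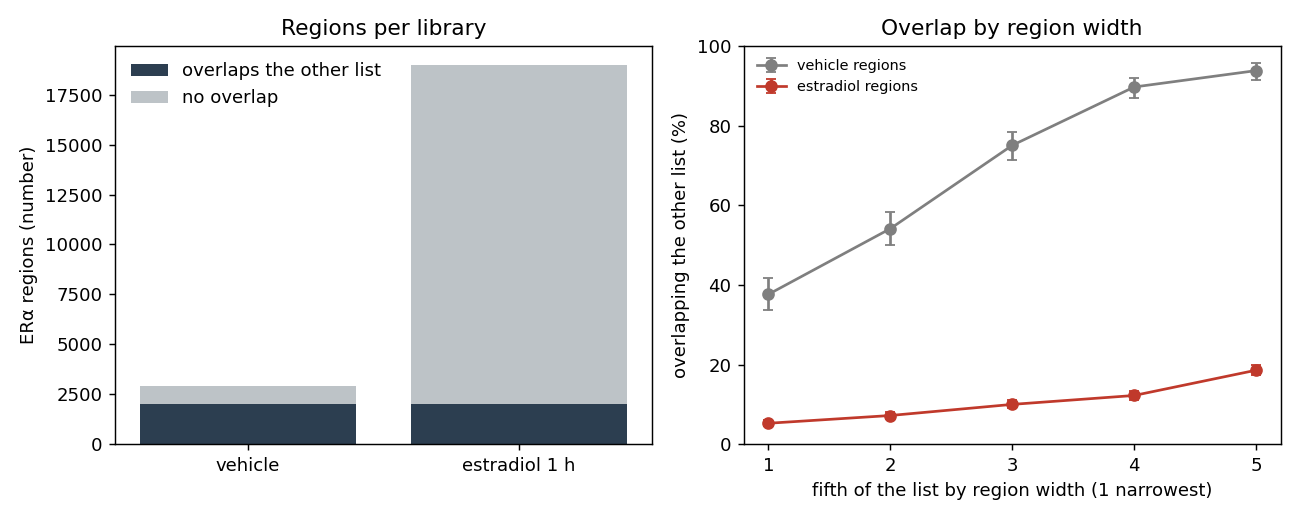
Left, number of ERα regions per library (vertical axis), with regions that overlap the other list in dark and the rest in light grey. Right, share of regions overlapping the other list (percent) by quintile of region width, with 95% exact binomial intervals; for vehicle regions the share runs from 37.6% in the narrowest to 93.8% in the widest quintile, and for estradiol regions from 5.27% to 18.6%.

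Regions were wider after estradiol. The median width was 352 bp (95% interval 349 to 354 bp) in the estradiol list and 248 bp (243 to 254 bp) in the vehicle list. The narrowest listed width also differed between the libraries. It was 120 bp in the vehicle list, where 57 regions had it, and 149 bp in the estradiol list, where 170 regions had it. At the same 2013 sites the estradiol region had a median width of 421 bp and the vehicle region 280 bp. The median paired difference was 134 bp (95% interval 127 to 142 bp), and the estradiol region was the wider at 1774 sites (88.1%; two-sided sign-flip permutation p = 1e-05, the smallest possible). Estradiol regions without a vehicle counterpart had a median width of 345 bp, 77 bp below the 422 bp of shared estradiol regions (two-sided permutation p = 1e-05).

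**Figure D2:**
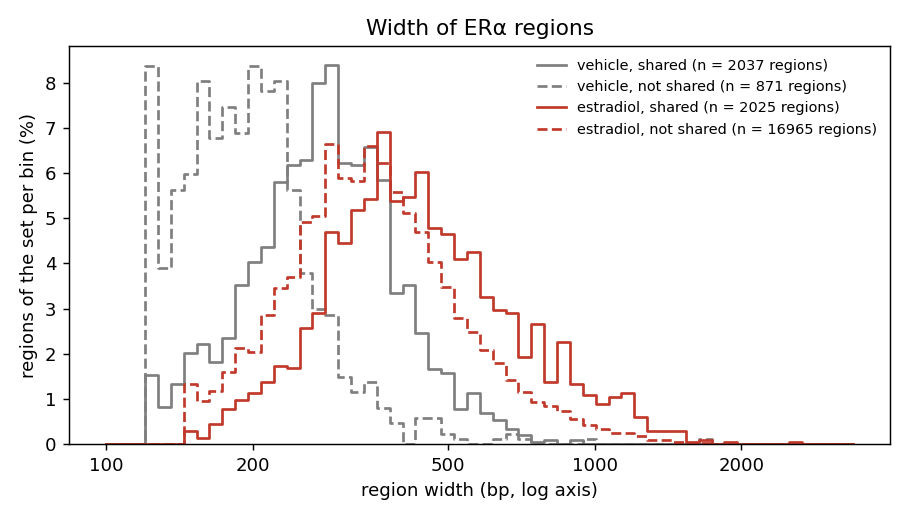
Distribution of ERα region width (horizontal axis, bp, log scale) as the percentage of each set per bin, for shared (solid) and not shared (dashed) regions of the vehicle (grey) and estradiol (red) lists. Vehicle regions that were not shared are the narrowest set, with a median of 191 bp, and shared estradiol regions the widest, with a median of 422 bp.

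The widest individual sites included both shared and unmatched regions. The unmatched vehicle regions named here are not typical of their class, whose median width was 191 bp. The widest vehicle region, on chromosome 17 from 39984109 to 39985820 (1712 bp), had no estradiol counterpart, and the nearest estradiol region was 2259 kb away. The next widest vehicle region, on chromosome 17 from 36053140 to 36054101 (962 bp), was also unmatched, with an estradiol region 5.99 kb away. The other named vehicle regions were all shared. The region on chromosome 17 from 12861448 to 12862378 (931 bp) overlapped a 1290 bp estradiol region. The region on chromosome 15 from 31971947 to 31972866 (920 bp) overlapped one of 1114 bp. The region on chromosome 11 from 98636432 to 98637249 (818 bp) overlapped one of 642 bp, which is narrower. Among the 5 widest estradiol regions, only that on chromosome 19 from 23208218 to 23210723 (2506 bp) had a vehicle counterpart, of 501 bp. The widest of all lay on chromosome 8 from 129189513 to 129192915 (3403 bp), with the nearest vehicle region 30.9 kb away. The other estradiol regions lay on chromosome 9 from 36837380 to 36839671 (2292 bp), chromosome 4 from 124626696 to 124628737 (2042 bp) and chromosome 1 from 135994900 to 135996868 (1969 bp). Their nearest vehicle regions were 22.7 kb, 7.72 kb and 44.8 kb away. Genes at these positions were not assigned.

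ERα regions were grouped along the chromosomes rather than spread evenly. In the estradiol list 10209 regions (53.8%, 95% interval 53.0 to 54.5%) had another region within 10 kb, against 15.3% on average and 16.6% at most in 1000 random placements (one-sided permutation p = 0.001). In the vehicle list 444 regions (15.3%, 14.0 to 16.6%) had such a neighbour, against 2.60% on average and 4.06% at most in the placements (one-sided permutation p = 0.001). With regions within 500 bp merged, the shares were 48.0% of 17750 estradiol and 12.6% of 2863 vehicle regions. The placements then averaged 14.4% and 2.55%. The libraries cannot be compared directly in this measure because it grows with the number of regions. When 2908 estradiol regions were drawn at random 100 times, the share had a median of 14.2% and ran from 12.1 to 16.5%, a range that holds the vehicle value.

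Joining regions at most 12.5 kb apart gave 478 clusters of 5 or more estradiol regions, which held 3207 regions (16.9% of the list). Random placement gave 1.86 such clusters on average and at most 6 in 100 placements. The vehicle list held 1 such cluster, and its 100 placements gave at most 0. The counts of the 2 lists cannot be compared directly, because a longer list forms more clusters. No cluster count was made on equal numbers of regions or after merging regions within 500 bp. The estradiol clusters named next were chosen after their values were seen. The largest by number of estradiol regions spanned 60.3 kb on chromosome 1, from 74040671 to 74100938, and held 23 estradiol regions and 4 vehicle regions. Some of those 23 lay less than 500 bp apart. The second lay on chromosome 16 from 34931485 to 34996539 with 21 estradiol and 2 vehicle regions. Clusters of 19 estradiol regions lay on chromosome 6 from 50887049 to 50962894, with 4 vehicle regions, and on chromosome 17 from 84272156 to 84354194, with 3. A cluster of 18 lay on chromosome 2 from 167644262 to 167703515 with 1 vehicle region. Of the 478 clusters, 231 (48.3%, 43.8 to 52.9%) contained at least 1 vehicle region. That share grows with the span of a cluster and its number of regions, and no chance value was computed for it. Counted by region, 10.9% of the estradiol regions in clusters were shared with vehicle and 11.6% of the 8010 isolated ones were, a difference that did not pass the test (odds ratio 0.936, Fisher's exact p = 0.340). This comparison was not matched on width. Estradiol regions shared with vehicle had a neighbour within 10 kb in 50.7% of cases and those without a counterpart in 54.1% (odds ratio 0.870, two-sided Fisher's exact p = 0.00320). The odds ratio was 1.05 when regions within 500 bp counted as shared (two-sided Fisher's exact p = 0.333). It was 0.689 when estradiol-only regions were matched on width (two-sided Fisher's exact p = 4.9e-09).

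**Figure D3:**
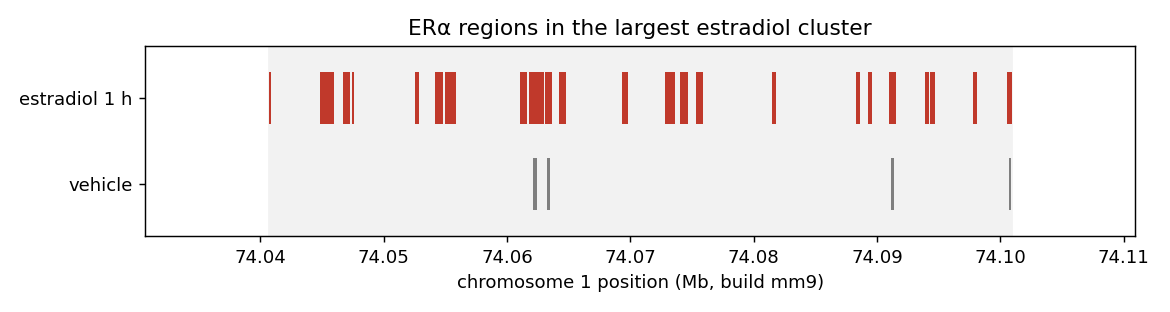
Map of the largest estradiol cluster by number of regions, on chromosome 1 (horizontal axis, position in Mb, build mm9), with each ERα region drawn to scale for the estradiol (red) and vehicle (grey) libraries and the extent of the cluster shaded. The cluster holds 23 estradiol and 4 vehicle regions over 60.3 kb.

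The share of the list differed between the libraries on chromosomes X and 11 by the adjusted test. The test treats the lists as separate samples of independent regions. However, 2037 vehicle regions overlap an estradiol region and regions lie in groups, so its p-values are descriptive. On the X chromosome there were 12 vehicle regions (0.413% of the list, 95% interval 0.213 to 0.720%) and 211 estradiol regions (1.11%, 0.967 to 1.27%). The odds ratio of vehicle to estradiol was 0.369 (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00298). Both lists were sparse on X, with 1.32 estradiol regions per Mb against 7.91 on the autosomes, and 0.0748 vehicle regions per Mb against 1.22. Of the X-linked vehicle regions, 4 had an estradiol counterpart. Chromosome 11 was the most densely bound in both lists, with 12.01 estradiol and 2.22 vehicle regions per Mb. It took a larger share of the vehicle list (9.04%) than of the estradiol list (7.50%; odds ratio 1.23, Fisher's exact test, adjusted p = 0.0451). The other 18 chromosomes did not pass the adjusted test, including chromosome 18 (2.44% of vehicle and 3.26% of estradiol regions, odds ratio 0.742, Fisher's exact test, adjusted p = 0.111). Both calls of Fisher's exact test were lost when each list was restricted to regions at least as wide as its median (odds ratio 0.182, adjusted p = 0.0957 for X; 1.24 and 0.254 for chromosome 11) and when the vehicle list was set against the 2908 widest estradiol regions (odds ratio 0.749, adjusted p = 0.984 for X; 1.25 and 0.434 for chromosome 11). The odds ratio of chromosome 11 was thus as large with fewer regions. That of X lay closer to 1 against the widest estradiol regions. Under the median restriction the X value rested on 2 vehicle regions (0.137% of 1462, 95% interval 0.0166 to 0.493%) and 71 estradiol ones (0.747% of 9500, 0.584 to 0.942%). These are too few to tell it from the whole-list value. The X difference kept its direction there, with an unadjusted Fisher's exact p of 0.00479, and its call was lost only after adjustment.

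**Figure D4:**
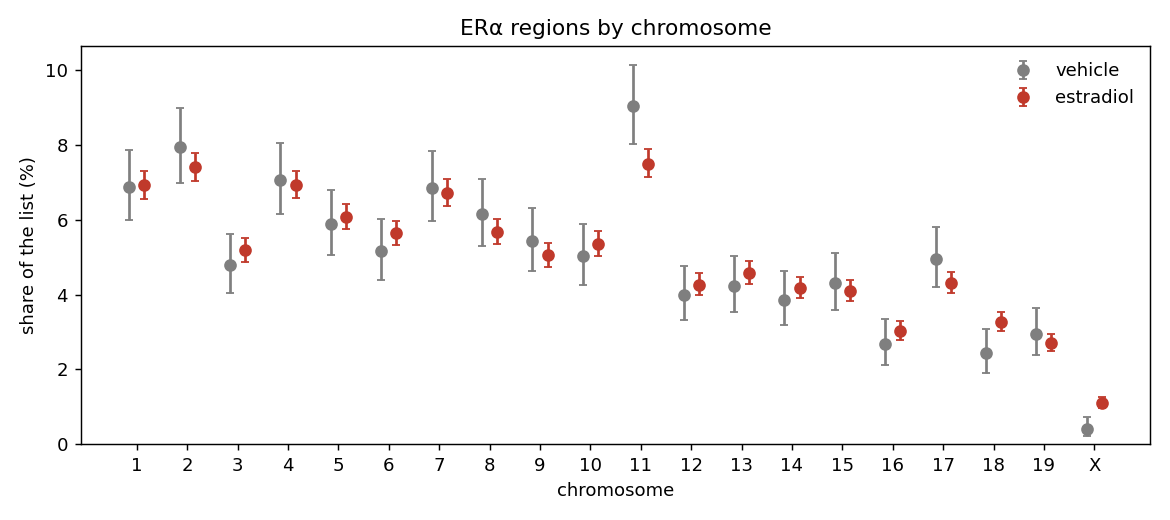
Share of each ERα list (vertical axis, percent) on each chromosome for the vehicle (grey) and estradiol (red) libraries; bars are 95% exact binomial intervals over regions. The X chromosome holds 0.413% of vehicle and 1.11% of estradiol regions, and chromosome 11 holds 9.04% and 7.50%.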

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

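The neighbour measure, the alternatives to its share in each list, and the shifted-region, minimum-width and chromosome alternatives were chosen after seeing the data; the others were set before, and 2 of them, set for shared against estradiol-only regions, were applied to the neighbour odds ratio. Of 44 alternative values, 35 kept their direction and side of the threshold or stayed near the reported value. Those 35 include the values for the autosomes and X alone, which could not change because both lists hold only these chromosomes. The tolerance for staying near is not stated here, so the count is descriptive and does not measure robustness. Under every overlap criterion run, 61.2 to 74.0% of vehicle regions and 7.86 to 11.8% of estradiol regions were shared, each above all 1000 placements. Keeping regions at least as wide as the median of their list left, by construction, 1462 vehicle and 9500 estradiol regions. Under that restriction the X odds ratio was 0.182, from 2 vehicle and 71 estradiol regions on X. It kept its direction but no longer passed the adjusted test (Fisher's exact test, unadjusted p = 0.00479, adjusted p = 0.0957). Against only the widest estradiol regions the X odds ratio was 0.749. The chromosome 11 call was also lost under these restrictions, with odds ratios of 1.24 and 1.25 against 1.23 and fewer regions. Merging regions within 500 bp gave 17750 estradiol and 2863 vehicle regions, a 6.20-fold difference, with an estradiol median width of 359 bp and covered length of 7.80 Mb. The odds ratio of having a neighbour, shared against estradiol-only, turned to 1.05 when regions within 500 bp counted as shared, a rule that itself adds neighbours of shared regions, and was 0.689 with estradiol-only regions matched on width. Random sets of 2908 estradiol regions had neighbours in 14.2% of cases. Alternatives set for motifs, k-mers, annotation and gene lists were not run without an mm9 sequence or annotation. Depth and calling threshold are unknown, so the excess of estradiol regions cannot be apportioned between binding and detection.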

Other observations

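Vehicle regions without an estradiol counterpart lay close to estradiol regions far more often than random sites would. Of these 871 regions, 80 (9.18%) had an estradiol region within 1 kb and 749 (86.0%) within 100 kb, and the median distance was 20.2 kb. Random placement gave 1.48% and 45.1% on average (one-sided permutation p = 0.001 for each, the smallest possible). Estradiol regions in clusters of 5 or more were wider, with a median of 412 bp, than the isolated ones, with a median of 324 bp; this difference was not tested.

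The tests on vehicle regions without a counterpart were chosen after the results were seen, as was the use of the width of shared and estradiol-only regions, a comparison set in advance, to weigh an explanation, and the overlap of the widest estradiol regions; the tests of the X share among the widest estradiol regions and of the paired width difference were written before. For the 871 unmatched vehicle regions, an even scatter of background over the chromosomes is argued against as the whole account, because 34.3% had an estradiol region within 10 kb and the highest of 1000 random placements was 14.4%. Weak regions near the detection limit remain a candidate explanation: 62.4% of the narrowest quintile lacked a counterpart against 6.20% of the widest, although width is only a stand-in for signal height. Background that follows open chromatin, and a true loss of receptor at some sites after estradiol, stay open, since neither list gives signal heights. The 1712 bp region on chromosome 17 is an exception to the narrow class and would merit a look at its reads for repeat or multicopy sequence, which was not tested.

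For the scarcity of X-linked vehicle regions, the test written before the result was seen came out as the account that only the widest sites are listed without estradiol predicts: 0.550% (95% interval 0.315 to 0.892%) of the 2908 widest estradiol regions lay on X, not separable from the vehicle share of 0.413% (Fisher's exact p = 0.571), against 1.21% (1.05 to 1.39%) of the remaining 16082. The premise of that account is argued against by a test chosen afterwards, which does not measure X: 581 of those 2908 widest regions (20.0%, 18.5 to 21.5%) overlapped a vehicle region, so the vehicle list is not simply the widest sites. The X-linked vehicle regions were themselves narrow, with a median of 201 bp against 248 bp for the whole vehicle list, and 4 of the 12 had an estradiol counterpart. X-linked estradiol regions were narrow too, with a median of 308 bp against 352 bp on the autosomes (two-sided permutation p = 0.00048). Among regions at least as wide as the median of their list the X odds ratio was 0.182, against 0.369 in the whole lists. It rested on 2 vehicle regions on X of 1462 (0.137%, 95% interval 0.0166 to 0.493%) and 71 estradiol ones of 9500 (0.747%, 0.584 to 0.942%). The X difference thus kept its direction among wide regions. Each list was cut at its own median, so the lists were matched neither on width nor on number of regions. The account does not forbid a lower vehicle share under such a cut, so this value cannot weigh on it. A partial effect of site strength, in which wider sites are only more often listed, and a selective gain of X-linked sites with estradiol both stay open.

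The greater width of estradiol regions is not accounted for by a constant addition of 29 bp, the difference between the minimum widths of the lists. The same sites differed by 134 bp (127 to 142 bp). A larger constant addition to every region, such as a longer fragment length used in calling, stays open. Minimum widths also depend on the calling rule and threshold, which are unknown, so they cannot give the size of such an addition. Nor is the greater width accounted for by wider sites among those found only with estradiol, since these were narrower than the shared ones (difference -77 bp). Greater depth or enrichment of the estradiol library and more receptor at each site could both widen a region, and they cannot be separated without reads or signal, which keeps both open.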
